A study of Homo sapiens with 18 samples.

How the data were processed

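RNA from the esophageal squamous cell carcinoma lines TE-1 and TE-8 was measured on 18 Illumina BeadChip arrays. Per the labels' protocols, total RNA was isolated with a mirVana kit, and biotin-labelled cRNA was prepared from 500 ng of total RNA with a TotalPrep kit. The labels do not state how the first strand was primed. The submitters' processing notes name BeadStudio, with the version not stated, and speak of an export per gene, while the table holds 47230 probes.

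The deposited table of non-normalized values gives a linear intensity per probe and array. Its array minima lie between 73.0 and 107 and its medians differ, so the values are neither background-subtracted nor scaled between arrays, and the table holds no detection p-values. The deposited series table holds log2 values that the authors had quantile normalized within each set of 6 arrays (TE-1 24 h, TE-1 72 h, TE-8), as seen from sorted values that differ by at most 0.002 within a set. Its array medians are 6.708, 6.899 and 7.157 in the 3 sets, so its levels cannot be compared between sets, and it was used only as an alternative for the knockdown comparisons. Each of its columns correlated best with the same array's signals in the intensity table, and 0 columns of values were left without a sample.

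Probes were named from the RefSeq gene table of build GRCh38.p14, which served for names and gene neighbours only. Of the probes, 27607 took the name of their RefSeq accession, 3387 had a current symbol, 1387 a unique older symbol, and 11579 kept the symbol of the file. VTRNA2-1 is listed under its older symbol MIR886. The remaining 3270 probes had no symbol and were tested apart. The 43960 named probes stood for 30695 genes, 8816 of them with more than 1 probe, for which the probe with the highest mean signal was taken.

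Groups were taken from the labels: TE-1 control and knockdown at 24 h and 72 h, and TE-8 control and knockdown with no time given, 3 arrays each. Median signals of 102 to 161 stand little above the array minima, so changes of dim genes are compressed, and the number of arrays limits the precision of all genes. A log2 level of 6.52, the 60th percentile of all probes, was taken as the dim level after the data were examined, and 16131 genes had a group mean above it. Where the lower group of a comparison lies under it, the difference is a lower bound.

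Signals were background corrected by normexp with an offset of 50, quantile normalized over the 18 arrays and put on the log2 scale, with no filter. A correction by detection p-values (neqc) and a detection filter had been chosen before the data were examined, with this route as the stated substitute for a table without detection p-values. A linear model with a mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 12 residual and 21.9 prior degrees of freedom. The comparisons were knockdown against control in each of the 3 settings, the mean of these effects, the 72 h minus the 24 h effect in TE-1, the TE-8 effect minus the mean TE-1 effect, TE-1 control 72 h minus 24 h, and TE-8 control minus the mean of the TE-1 controls. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 within each comparison. No array served as control in more than 1 knockdown comparison. Errors are standard errors of the model unless named SD, and values given "at" a number are log2 differences. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

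The comparisons, the lists and the rule for named genes were fixed before the data were examined. The 26 lists were immediate early and AP-1 genes, NF-kB genes and targets, MYC targets, interferon-stimulated genes, integrated stress response genes, ER chaperones and the unfolded protein response, p53 targets and apoptosis genes, DNA replication and S phase, G2/M and mitosis, histones, squamous keratins and differentiation, epithelial-mesenchymal genes, epithelial junction genes, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, nuclear encoded respiratory chain genes, cytosolic ribosomal proteins, heat shock, NRF2 and oxidative stress, vault particle and RNA polymerase III, the PKR pathway, TGF-beta targets, and fibroblast, endothelial and leukocyte markers. Some genes stand on more than 1 list. Each was tested against the other genes with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes.

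Named genes were VTRNA2-1, VTRNA1-1, EIF2AK2, FOS, MYC and NFKB1 always. For each knockdown comparison they were the 8 largest rises and 8 largest falls among called genes whose 3 knockdown arrays all lay on one side of the 3 control arrays. For the mean effect they were the 8 largest of each direction with the same sign in all 3 settings, for each difference of effects 5 of each, for the time and line comparisons 6 of each, and from each list up to 4 members with the smallest adjusted p. Symbols starting with LOC, HS., KIAA or FLJ, symbols with "orf" in them and probes without a symbol were passed over.

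Alternatives were no background correction (log2 of the signal plus 16), median scaling, normalization within each line, the authors' table, only the compared arrays in the fit, the replicate number as a block, all probes, the mean of a gene's probes, an intensity trend in eBayes, and each array left out in turn. Those added after the data were examined were leaving out genes under the dim level or under the 75th percentile, a normexp offset of 16, normalization within each set of 6 arrays, and leaving out TE-1 control 24 h replicate 2 together with TE-1 control 72 h replicate 2. The method was tested on simulated data with independent noise of the same spread in all groups. Changes were put only into genes above the dim level. Of 100 genes changed by 0.5 on the log2 scale 79, 72 and 80 were called in the 3 knockdown comparisons. Of 100 changed by 1 all were called, with 8, 9 and 8 unchanged genes called. Unequal spread between groups and correlated genes were not simulated. Classes of RNA were taken from the gene symbols and the RefSeq table after the data were examined. Other splits of the same arrays were counted for each number of genes or lists, 10 for a comparison of 3 arrays with 3 and 100 drawn with a fixed seed for the others.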

Results

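Gene expression was measured on 18 Illumina BeadChip arrays, which read labelled copies of cellular RNA with 47230 probes, in TE-1 and TE-8, cell lines of esophageal squamous cell carcinoma. Knockdown cells had received an antisense oligonucleotide, a short nucleic acid that directs the breakdown of the RNA it pairs with, against nc886. nc886, also called vault RNA 2-1 (VTRNA2-1), is a short RNA polymerase III transcript known to bind the double-stranded RNA kinase PKR. Control cells had received an oligonucleotide against VTRNA1-1, a vault RNA of the same family, so each difference lies between cells given active oligonucleotides, and no untreated cells were among the samples. The arrays formed 6 groups of 3: TE-1 control and knockdown at 24 h, TE-1 control and knockdown at 72 h, and TE-8 control and knockdown, for which the labels give no time. Median probe signals ranged from 102 to 161 intensity units over the arrays and mean signals from 432 to 748. Correlations between replicate arrays ranged from 0.988 to 0.997 over the genes. The main axis of variation between arrays, with 69.6% of the variance, separated the lines, the next (17.1%) the times in TE-1, and the third (5.05%) the knockdown from the control arrays. TE-1 control 72 h replicate 2 stood apart from its group on the fourth axis, which held 2.25% of the variance. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, and the number of arrays limits their precision.

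The oligonucleotides' own targets were examined first, to ask whether each target was lower where it was attacked. VTRNA2-1 was lower on every knockdown array than on the control arrays of its setting. In TE-1 at 24 h its signal was 505 to 743 on the control arrays and 128 to 164 on the knockdown arrays. At 72 h it was 346 to 411 on the control and 156 to 171 on the knockdown arrays, and in TE-8 632 to 900 and 175 to 224. Its log2 level fell by 2.17 (SE 0.12, n = 3 per group, limma adjusted p = 9.68e-16) in TE-1 at 24 h, and was at -1.77 (adjusted p = 8.72e-13) at 72 h and at -2.19 (adjusted p = 2.34e-16) in TE-8. VTRNA1-1, the target in the control arms, was higher in TE-8 knockdown cells by 3.69 (adjusted p = 2.18e-22), with signals of 404 to 520 on the control and 4324 to 5591 on the knockdown arrays. In TE-1 its difference was 0.50 at 24 h (adjusted p = 0.00708) and 0.26 at 72 h (adjusted p = 0.22). There its signals were 126 to 166 on the control and 153 to 233 on the knockdown arrays at 24 h. At 72 h they were 135 to 162 and 165 to 192. These lie little above the array medians, so they cannot show how far the control oligonucleotide lowered VTRNA1-1 in TE-1. The call at 24 h was lost without TE-1 knockdown 24 h replicate 3, where the difference was 0.36.

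**Figure D1:**
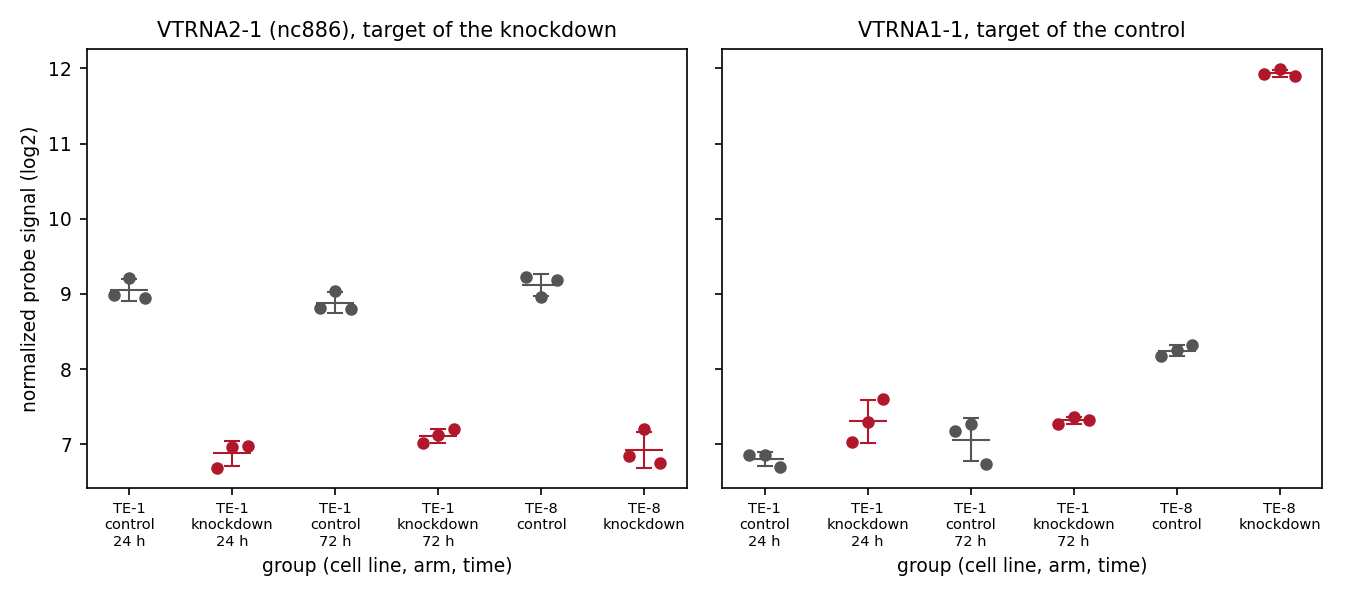
Normalized log2 probe signal (vertical axis) of VTRNA2-1 and VTRNA1-1 on each array (points) in the 6 groups (horizontal axis), grey for control and red for knockdown, with the mean and its SD as lines (n = 3). VTRNA2-1 was lower on all knockdown arrays than on the control arrays of the same setting, with mean differences of -2.17, -1.77 and -2.19.

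The TE-1 comparison at 24 h asked which genes differ in nc886 knockdown cells soon after treatment. Small nuclear RNAs, the RNA parts of the splicing machinery, made up all 8 of the largest rises named by the rule for genes. The U1 genes RNU1-3, RNVU1-7, RNVU1-18, RNU1-1 and RNU1-4 rose by 2.86, 2.84, 2.83, 2.59 and 2.33 on the log2 scale (for RNU1-1 6.04-fold, adjusted p = 6.3e-19). RNU4ATAC and RNU12 of the minor spliceosome rose by 2.69 (adjusted p = 2.74e-18) and 2.25 (adjusted p = 3.85e-15), and RNU5A-1 by 2.51 (adjusted p = 9.53e-16). Besides VTRNA2-1, DDX55, an RNA helicase, fell by 1.70 (adjusted p = 4.24e-15), PBX2, a homeobox transcription factor, by 1.31, and FARS2, the mitochondrial phenylalanyl-tRNA synthetase, was at -1.24. GCDH, an enzyme of lysine breakdown, fell by 1.07, GNPTG, which helps tag lysosomal enzymes, by 1.06, VCF1 by 1.09 and LFNG, a sugar transferase that modifies Notch, by 1.43. Only 1 of the 3 LFNG probes fell, and the mean over its probes was -0.55.

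Immediate early and AP-1 genes, the transcription factors and regulators first induced by growth and stress signals, rose as a group in TE-1 at 24 h. Of 32 measured members 24 rose and 0 fell (26 and 0 adjusted over the list alone, camera adjusted p = 1.23e-34), with FOS up 2.36-fold, KLF10 at 1.25, FOSB at 1.15 and KLF4 at 0.96. MYC, a growth-promoting transcription factor on the same list, rose by 0.86 (adjusted p = 6.12e-06). NF-kB genes and targets shifted up, with 11 of 34 risen and 1 fallen (14 and 1 adjusted over the list alone, adjusted p = 9.47e-09). Among them the cytokine IL6 was at 1.28 and the inhibitors TNFAIP3 and NFKBIE were at 0.74 and 0.80. Integrated stress response genes, induced by the factor ATF4, shifted up with 13 of 34 risen and 0 fallen (13 and 0 adjusted over the list alone, adjusted p = 4.16e-10), including STC2 at 1.02, TRIB3 at 0.63 and PPP1R15A at 0.60. TGF-beta targets shifted up with 8 of 20 risen and 1 fallen (8 and 1 adjusted over the list alone, adjusted p = 1.08e-05). The differentiation inhibitor ID2 was at 1.87 and the matrix protein gene CCN2 at 0.98. Histone genes shifted up with 7 of 19 risen and 0 fallen (7 and 1 adjusted over the list alone, adjusted p = 2.13e-06), for example H4C8 at 0.94, H2AC6 at 0.92 and H2BC21 at 0.82. These 5 lists were also called with an estimated correlation, with adjusted p from 0.000347 to 0.0437.

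Another 6 lists in TE-1 at 24 h were called with the preset correlation alone. Of the nuclear encoded respiratory chain genes 1 of 38 fell, NDUFB7 at -0.34 (0 adjusted over the list alone, adjusted p = 7.3e-05, against adjusted p = 0.247 with an estimated correlation). The NDUFB7 call was lost without TE-1 control 24 h replicates 1 (-0.35) and 2 (-0.28) and without TE-1 knockdown 24 h replicates 1 (-0.33), 2 (-0.31) and 3 (-0.37). Of the DNA replication and S phase genes 3 of 34 fell and 1 rose (7 and 4 adjusted over the list alone, adjusted p = 0.0237), with the histone messenger binding protein SLBP at -0.55. The list's call was lost at adjusted p = 0.0589 with an estimated correlation. ER chaperone and unfolded protein response genes had 4 of 23 risen (4 adjusted over the list alone, adjusted p = 0.0235, and adjusted p = 0.218 with an estimated correlation). The p53 targets and apoptosis genes had 5 of 30 risen and 2 fallen (6 and 2 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.142 with an estimated correlation), with BCL2L11 at 1.17 (mean over its probes 0.71), CDKN1A at 0.84 (1 of 2 probes risen, mean 0.47) and GADD45A at 0.79. Epithelial-mesenchymal genes had 7 of 35 risen and 1 fallen (7 and 1 adjusted over the list alone, adjusted p = 0.0338, and adjusted p = 0.218 with an estimated correlation), among them SNAI2 at 1.18 and TWIST1 at 0.51. Epithelial junction genes had 6 of 28 risen and 1 fallen (8 and 2 adjusted over the list alone, adjusted p = 0.0393, and adjusted p = 0.273 with an estimated correlation), with TJP3 at -0.68 and EHF at 0.55. Under median scaling the mean shifts of the last 4 of these lists were -0.05, 0.01, -0.00 and -0.05, none of them called, and their adjusted p reached 0.991, 0.287, 0.449 and 0.879 from lows of 0.00301, 0.0252, 0.00407 and 0.0112 over 15 alternatives. The S phase list ranged from 5.4e-06 to 0.0858. Leaving out 1 array ended calls too: for ER genes TE-1 control 24 h replicate 2 (adjusted p = 0.0873) or TE-1 knockdown 24 h replicate 2 (0.18), and for S phase genes control replicate 3 (0.0661) or knockdown replicate 1 (0.0563). For p53 targets these were control replicate 1 (0.0534), control replicate 3 (0.0601) and knockdown replicate 3 (0.0642), for epithelial-mesenchymal genes control replicate 2 (0.224) and knockdown replicate 2 (0.0543), and for junction genes control replicates 1 (0.0594) and 2 (0.218) and knockdown replicate 2 (0.129).

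In all, limma called 1967 of 30695 genes in TE-1 at 24 h, 1040 higher and 927 lower in knockdown cells, of which 46 rose and 13 fell at least 2-fold. For 20.6% of all genes the 3 knockdown arrays lay wholly on one side of the 3 control arrays, where chance gives 10%. Without TE-1 control 24 h replicate 1 the count was 1306 and without TE-1 knockdown 24 h replicate 1 it was 1310. With a normexp offset of 16 it was 1091, and under median scaling 22.8% of the called genes were higher, against 52.9%.

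The TE-1 comparison at 72 h asked the same question later after treatment. GADD45G, a stress sensor that slows growth, rose by 2.23 (4.68-fold, adjusted p = 2.92e-15), ID2 by 1.94 (adjusted p = 1.49e-11) and RASD1, a Ras-related GTPase, by 1.63 (adjusted p = 1.74e-12). Small nuclear RNAs were again among the largest rises, with RNU4ATAC at 1.89, RNU5A-1 at 1.54, RNU1-1 at 1.53 and RNU1-3 at 1.49. Besides VTRNA2-1, the small RNAs SNORD11B, a small nucleolar RNA, and RNY4, a Y RNA, fell by 1.23 (adjusted p = 3.28e-09) and 1.16 (adjusted p = 4.1e-07), and MIR1974 by 1.07. Among coding genes ETNK1, an ethanolamine kinase, fell by 1.19, MYSM1, a histone deubiquitinase, by 1.11, HSD3B1, an enzyme of steroid synthesis, by 1.07, and GPRIN2 by 1.04. The mean over the ETNK1 probes was -0.50, and in the authors' table MYSM1 was at -0.72 and HSD3B1 at -0.66.

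The lists that rose in TE-1 at 72 h again began with immediate early and AP-1 genes, of which 14 of 32 rose and 0 fell (16 and 1 adjusted over the list alone, adjusted p = 1.16e-10), including FOSB at 1.25, CCN2 at 1.14 and FOS at 0.87. Integrated stress response genes had 13 of 34 risen and 3 fallen (18 and 3 adjusted over the list alone, adjusted p = 2.34e-08), with STC2 at 1.22 and CEBPG and NUPR1 both at 0.89. NF-kB genes and targets had 13 of 34 risen and 1 fallen (15 and 1 adjusted over the list alone, adjusted p = 2.69e-07), with the chemokines CXCL8 at 1.04 and CXCL2 at 0.75 and the cytokine IL1A at 0.73. TGF-beta targets had 7 of 20 risen and 1 fallen (10 and 2 adjusted over the list alone, adjusted p = 3.74e-07), with the cell cycle inhibitor CDKN2B at 0.87. Interferon-stimulated genes had 8 of 38 risen and 0 fallen (11 and 1 adjusted over the list alone, adjusted p = 6.83e-06), with the antiviral GTPase MX1 at 0.96, IFI6 at 0.59 and the RNA sensor IFIH1 at 0.58. Epithelial-mesenchymal genes had 8 of 35 risen and 0 fallen (8 and 0 adjusted over the list alone, adjusted p = 3.68e-05), with the actin gene ACTA2 at 1.14 and the actin binding protein TAGLN at 1.29 (mean over its probes 0.78). Histone genes had 5 of 19 risen (8 risen and 1 fallen adjusted over the list alone, adjusted p = 0.000739), with H2AC8 at 0.69. The p53 targets and apoptosis genes had 6 of 30 risen (6 adjusted over the list alone, adjusted p = 0.00316), with GADD45B at 0.85, while the probes of CDKN1A went both ways, at 0.90 and -0.48. Squamous keratins and differentiation genes had 5 of 45 risen (5 adjusted over the list alone, adjusted p = 0.0118), namely LCN2, an iron-scavenging protein, at 1.44, the keratins KRT17 at 1.07 and KRT16 at 0.60, TP63, a regulator of squamous cells, at 0.49 (mean over its probes 0.23) and CNFN at 0.43, which is named after its value was seen.

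Lists of growth and division genes shifted down in TE-1 at 72 h. MYC targets had 7 of 30 fallen and 2 risen (12 and 2 adjusted over the list alone, adjusted p = 2.09e-06), with SRM, which makes the polyamine spermidine, at -0.81 and CCND2, a cyclin of the start of the cell cycle, at 0.70. MYC itself rose by 0.45 (adjusted p = 0.0154), a call that was lost with a normexp offset of 16, without TE-1 control 72 h replicate 2 (0.40) and without TE-1 knockdown 72 h replicate 3 (0.43). DNA replication and S phase genes had 10 of 34 fallen and 0 risen (11 and 0 adjusted over the list alone, adjusted p = 2.88e-07), with the thymidine kinase TK1 at -0.58 and the helicase subunit MCM7 at -0.41. G2/M and mitosis genes had 5 of 38 fallen and 0 risen (8 and 0 adjusted over the list alone, adjusted p = 9.36e-07), with the spindle protein gene DLGAP5 at -0.44. The DLGAP5 call was lost with a normexp offset of 16, under median scaling (-0.36) and without TE-1 knockdown 72 h replicate 3 (-0.39). The 9 lists that rose and these 3 were also called with an estimated correlation, with adjusted p from 0.0019 to 0.0263.

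A further 4 lists in TE-1 at 72 h were called with the preset correlation alone. Respiratory chain genes had 4 of 38 fallen (4 adjusted over the list alone, adjusted p = 8.52e-05, and adjusted p = 0.162 with an estimated correlation), with CYC1 at -0.40, which was not called under median scaling (-0.39). Fatty acid synthesis genes had 4 of 20 risen and 1 fallen (5 and 1 adjusted over the list alone, adjusted p = 0.0154, and adjusted p = 0.162 with an estimated correlation), with the desaturase SCD at 1.22 and the carboxylase ACACB at 0.53. Heat shock genes shifted down as a list, by a median of -0.16, with 2 of 23 risen and 2 fallen (3 and 5 adjusted over the list alone, adjusted p = 0.0154, and adjusted p = 0.0526 with an estimated correlation). The chaperone HSPA1B went the other way, at 0.56. Epithelial junction genes shifted up, by a median of 0.11, with 4 of 28 risen and 1 fallen (5 and 1 adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.189 with an estimated correlation). The 1 fallen gene was the keratin KRT8, at -0.71. Without TE-1 control 72 h replicate 2 the calls of the fatty acid, heat shock and junction lists were lost (adjusted p = 0.0561, 0.0524 and 0.1), and the junction list also lost its call without TE-1 knockdown 72 h replicates 1 (0.115) and 3 (0.0637). Over 15 alternatives the adjusted p ranged from 0.000341 to 0.0634, from 0.00159 to 0.0524 and from 0.0047 to 0.115 for these 3 lists.

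In TE-1 at 72 h limma called 2425 genes, 1401 higher and 1024 lower, of which 32 rose and 12 fell at least 2-fold. The arrays of the groups did not overlap for 19.6% of genes, where chance gives 10%. The count was 1471 without TE-1 control 72 h replicate 2, 1293 with a normexp offset of 16 and 976 with only these 6 arrays in the fit. Under median scaling 87.2% of the called genes were higher, against 57.8%.

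The TE-8 comparison asked whether a second line responds. The largest rises named were those of RNU12 at 3.96 (15.5-fold), VTRNA1-2 at 3.95, VTRNA1-1 at 3.69 and RPPH1, the RNA of ribonuclease P, at 3.27 (each adjusted p = 2.18e-22). VTRNA1-1 is the target of the control oligonucleotide, so its difference may be a fall in the control cells. Without untreated cells this cannot be told apart from a rise in the knockdown cells. Whether the control oligonucleotide also lowered VTRNA1-2 was not tested. RNU5A-1 rose by 2.89 (adjusted p = 5.63e-18) and RNU4ATAC by 2.80 (adjusted p = 4.02e-19). IFNB1, the gene of interferon beta, rose 7.97-fold (adjusted p = 7.55e-22), and CXCL8, a chemokine that draws neutrophils, by 2.85 (7.2-fold, adjusted p = 5.78e-16). PBX2 fell by 1.85 (adjusted p = 2.9e-15), DDX55 by 1.82 (adjusted p = 2.34e-16), EXT1, an enzyme that builds heparan sulfate, by 1.64, PPP2R5E, a subunit of protein phosphatase 2A, by 1.62 and VCF1 by 1.61, while CTDSPL, a phosphatase, was at -1.50. LFNG fell by 1.62, with a mean over its probes of -0.48.

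Immediate early and AP-1 genes rose most widely in TE-8 too, with 26 of 32 risen and 0 fallen (27 and 0 adjusted over the list alone, adjusted p = 5.04e-43). JUN was at 2.36, FOSB at 1.76, DUSP6, which switches off ERK kinases, at 1.60, KLF6 at 1.57, FOS at 1.43 (adjusted p = 4.73e-12) and MYC at 1.20 (adjusted p = 1.71e-09). NF-kB genes and targets had 16 of 34 risen and 1 fallen (17 and 1 adjusted over the list alone, adjusted p = 6.53e-17), with IL6 at 2.68 (a lower bound, as its control level lay under the dim level), IL1A at 2.29 and PTGS2, which starts prostaglandin synthesis, at 1.87. Histone genes had 8 of 19 risen and 0 fallen (12 and 0 adjusted over the list alone, adjusted p = 1.62e-10), with H2BC21 at 1.45, H2BC5 at 1.43 (mean over its probes 0.67) and H2BC12 at 1.05. TGF-beta targets had 9 of 20 risen and 1 fallen (10 and 3 adjusted over the list alone, adjusted p = 6.54e-06), with ID2 at 2.09, CCN2 at 1.11 and the receptor decoy BAMBI at 0.83. Interferon-stimulated genes had 12 of 38 risen and 0 fallen (14 and 1 adjusted over the list alone, adjusted p = 2.43e-05), with IFIT2 at 1.60, the RNA sensor regulator DHX58 at 0.83 and the interferon response factor IRF9 at 0.80. The p53 targets and apoptosis genes had 7 of 30 risen and 1 fallen (7 and 1 adjusted over the list alone, adjusted p = 0.000509), with the cell death gene BCL2L11 at 1.56 and GADD45B at 0.99, while the probes of CDKN1A were at 1.54 and -0.51. These 6 lists were also called with an estimated correlation, with adjusted p from 0.000116 to 0.0311.

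Another 5 lists in TE-8 were called with the preset correlation alone. Integrated stress response genes had 11 of 34 risen and 1 fallen (12 and 2 adjusted over the list alone, adjusted p = 2.43e-05, and adjusted p = 0.104 with an estimated correlation), with PPP1R15A at 1.50, GDF15 at 1.28 and ATF3 at 1.10 (1 of 3 probes risen, mean 0.40). Respiratory chain genes had 6 of 38 fallen (8 adjusted over the list alone, adjusted p = 6.54e-06, and adjusted p = 0.156 with an estimated correlation), with SDHC at -0.49. Fatty acid synthesis genes had 7 of 20 fallen and 0 risen (9 and 1 adjusted over the list alone, adjusted p = 0.00133, and adjusted p = 0.104 with an estimated correlation), with the carboxylase ACACB at -0.57 and the phosphatase LPIN1 at -0.43. Cytosolic ribosomal proteins had 5 of 41 fallen and 1 risen (6 and 1 adjusted over the list alone, adjusted p = 0.00857, and adjusted p = 0.255 with an estimated correlation), with RPL15 at -0.46 and RPL22 at -0.41. Hypoxia and glycolysis genes had 7 of 34 fallen and 4 risen (13 and 5 adjusted over the list alone, adjusted p = 0.0212, and adjusted p = 0.118 with an estimated correlation), the glycolysis enzyme GPI at -0.52 and the collagen hydroxylase P4HA2 at -0.53 (mean over its probes -0.30) against ANKRD37 at 0.90 and ADM at 0.72. The hypoxia call was lost without TE-8 knockdown replicate 3 (adjusted p = 0.107) and with dim genes left out (0.0914), over a range from 0.00681 to 0.107, and the ribosomal call with dim genes left out (0.0582, range from 0.0015).

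In TE-8 limma called 3691 genes, 2041 higher and 1650 lower, of which 292 rose and 57 fell at least 2-fold. The arrays of the groups did not overlap for 31.8% of genes, where chance gives 10%. With only these 6 arrays in the fit the count was 5606. In all 3 knockdown comparisons the number of lists called with the preset correlation was set against other groupings of the same arrays, with 11 lists against up to 10 in TE-1 at 24 h, 16 against 9 at 72 h and 11 against 9 in TE-8. With an estimated correlation it was 5, 12 and 6 against 0 in each.

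**Figure D2:**
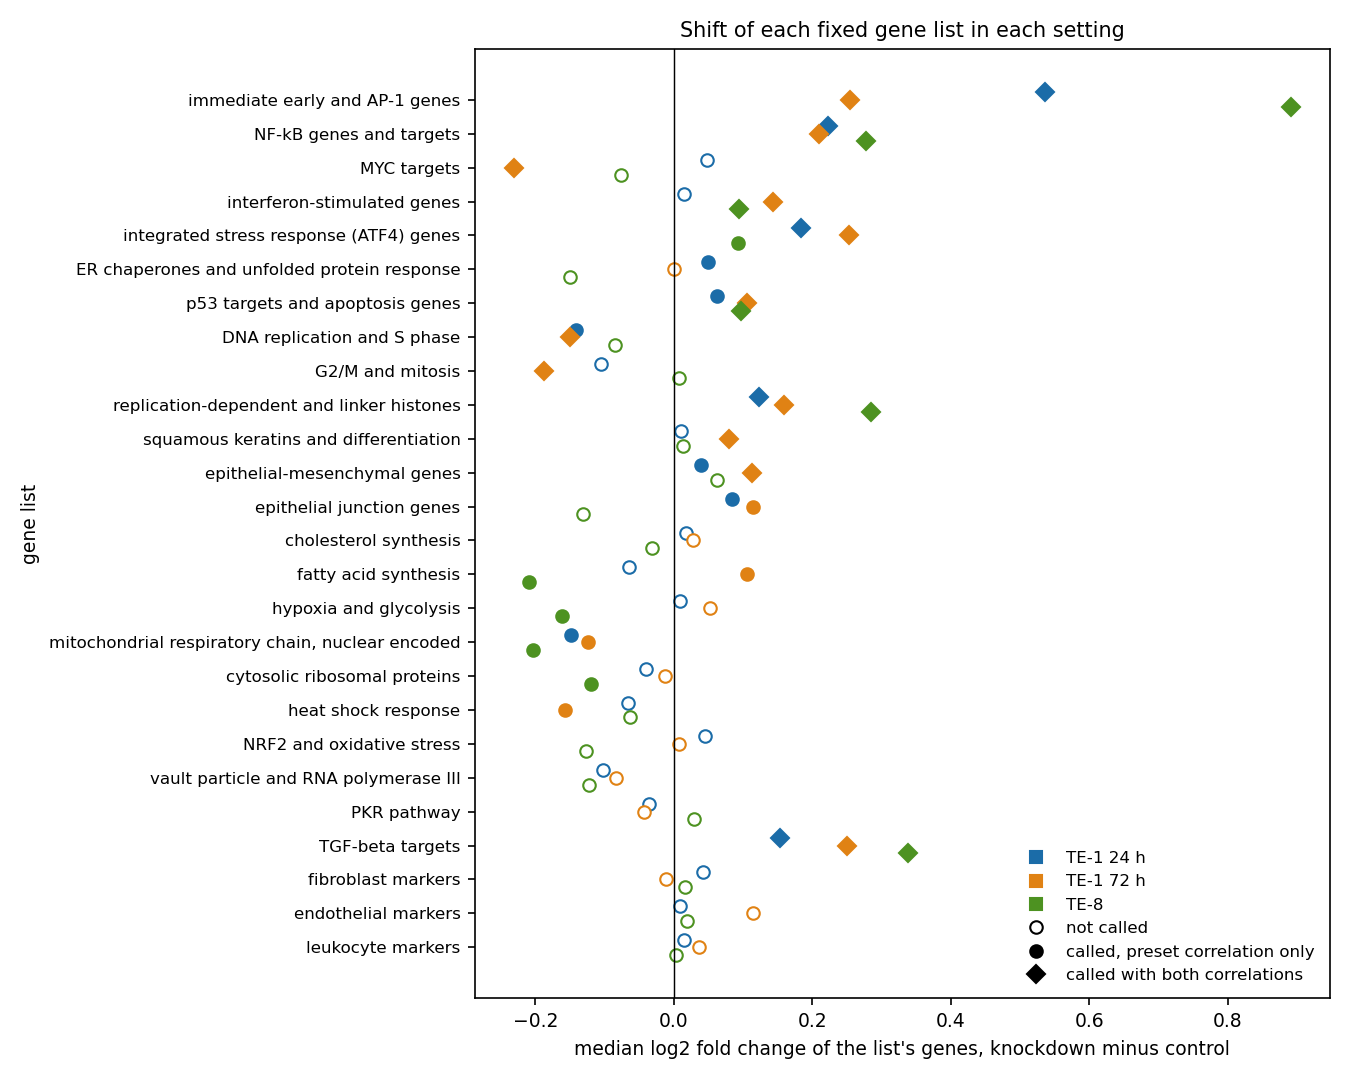
Median log2 change between knockdown and control (horizontal axis) of each gene list (vertical axis) in TE-1 at 24 h (blue), TE-1 at 72 h (orange) and TE-8 (green), with open points for lists not called, filled circles for calls with the preset correlation alone and diamonds for calls also made with an estimated correlation. The immediate early and AP-1 list, with 24, 14 and 26 of its 32 genes risen, has a diamond in all 3 settings.

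The remaining lists were called by camera in none of the 3 knockdown comparisons. Some had an adjusted p under 0.05 with fry, which does not compare a list with other genes. These were the PKR pathway at 72 h (0.0301) and in TE-8 (0.00124) and NRF2 genes in TE-8 (0.00541). At 72 h they were also endothelial (0.00718), leukocyte (0.0492) and vault (0.0492) genes. PKR pathway genes, of which 24 were measured, had 1, 1 and 5 risen and 1, 1 and 2 fallen in TE-1 at 24 h, at 72 h and in TE-8 (adjusted p = 0.864, 0.155 and 0.193). EIF2AK2, the gene of PKR itself, was at -0.07, 0.33 and -0.12 (adjusted p = 0.853, 0.0814 and 0.667), and NFKB1, an NF-kB subunit, at 0.02, 0.15 and -0.09 (adjusted p = 0.964, 0.497 and 0.767). Vault particle and RNA polymerase III genes, also 24, had 2, 0 and 3 risen and 0, 2 and 2 fallen (adjusted p = 0.44, 0.0967 and 0.813). Cholesterol synthesis genes, 25 in number, had 1, 2 and 3 risen and 2, 2 and 3 fallen (adjusted p = 0.938, 0.919 and 0.97). NRF2 and oxidative stress genes, 28 in number, had 3, 0 and 2 risen and 1, 1 and 5 fallen (adjusted p = 0.158, 0.912 and 0.0826). Among markers of cell types other than the lines, 12 fibroblast genes had 0, 2 and 0 risen (adjusted p = 0.864, 0.253 and 0.97), 12 endothelial genes 0, 1 and 0 risen and 1, 0 and 0 fallen (adjusted p = 0.967, 0.137 and 0.941), and 16 leukocyte genes 0, 2 and 2 risen (adjusted p = 0.602, 0.321 and 0.555). The leukocyte genes that rose included CSF1R at 0.86 and CD14 at 0.61 (1 of 2 probes risen, mean 0.39) in TE-1 at 72 h and CD68 at 1.13 in TE-8 (1 of 3 probes risen, mean 0.38). The median, mean and test of a list differed in sign for 3 lists in each knockdown comparison, 6 for the mean of settings, 5 for time and 3 for line, none of them called.

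The mean of the 3 knockdown effects asked which genes moved on average over both lines and both TE-1 times. RNU4ATAC was higher by 2.46 on average, RNU12 by 2.43, RNU5A-1 by 2.32, GADD45G by 2.04, RNU1-3 by 2.02, RNVU1-18 by 2.01, RNVU1-7 by 1.99 and ID2 by 1.97, each with the same sign in all 3 settings. VTRNA2-1 was lower by an average of -2.04, DDX55 of -1.42, PBX2 of -1.17, PPP2R5E, FARS2 and POC1B, a centriole protein gene, of -0.99, RRP7A, which takes part in ribosome assembly, of -0.98, and VCF1 of -0.96. The mean over the RRP7A probes was -0.50. FOS rose in each setting, 2.36-fold, 1.83-fold and 2.69-fold (adjusted p = 9.71e-10, 1.76e-06 and 4.73e-12). Of the annotated small nuclear RNAs, a class looked at after the values were seen, 11 of 17 rose and 0 fell in TE-1 at 24 h, 9 rose and 2 fell at 72 h (RNU6-1 at -0.63 and RNU6ATAC at -0.46), and 15 rose and 0 fell in TE-8, with median changes of 1.64, 0.53 and 1.64. Replication-dependent histone genes, a second class chosen so, had 22, 14 and 29 of 70 risen and 0 fallen.

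In this mean limma called 4478 genes, 2365 higher and 2113 lower. A call in the mean can rest on 1 setting. RN7SK, called at 0.38, was at -0.15 in TE-1 at 24 h, 0.09 at 72 h and 1.19 in TE-8. There were 181 genes risen in all 3 settings, where 3.16 would be if the settings were independent, and 76 fallen, where 1.66 would be. TE-1 at 24 h and TE-8 shared 525 risen and 408 fallen genes (69.2 and 49.8 if independent) and had 27 called in opposite directions (118 if independent). TE-1 at 24 h and 72 h shared 275 risen and 136 fallen genes (47.5 and 30.9) and had 92 in opposite directions (77.0). TE-1 at 72 h and TE-8 shared 329 risen and 166 fallen (93.2 and 55.0), with 190 opposite (143). All these expected numbers are over 30695 genes. With only genes above the dim level tested, 1915 of 1967, 2308 of 2425 and 3629 of 3691 calls were kept in TE-1 at 24 h, at 72 h and in TE-8. The expected numbers are thus too low, and an excess of opposite calls cannot be read from them. Over 16131 genes above the dim level the correlation of the log2 changes was 0.53 between TE-1 at 24 h and TE-8 (Spearman 0.41), 0.24 between the TE-1 times (0.158) and 0.21 between TE-1 at 72 h and TE-8 (0.15). These 3 correlations run across genes, which are not independent replicates. The count of fallen genes was 19 under median scaling, 31 with a normexp offset of 16, 35 with only the compared arrays in the fit and 46 without TE-1 control 24 h replicate 2 and 72 h replicate 2, and with the offset of 16 the count of risen genes was 107.

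**Figure D3:**
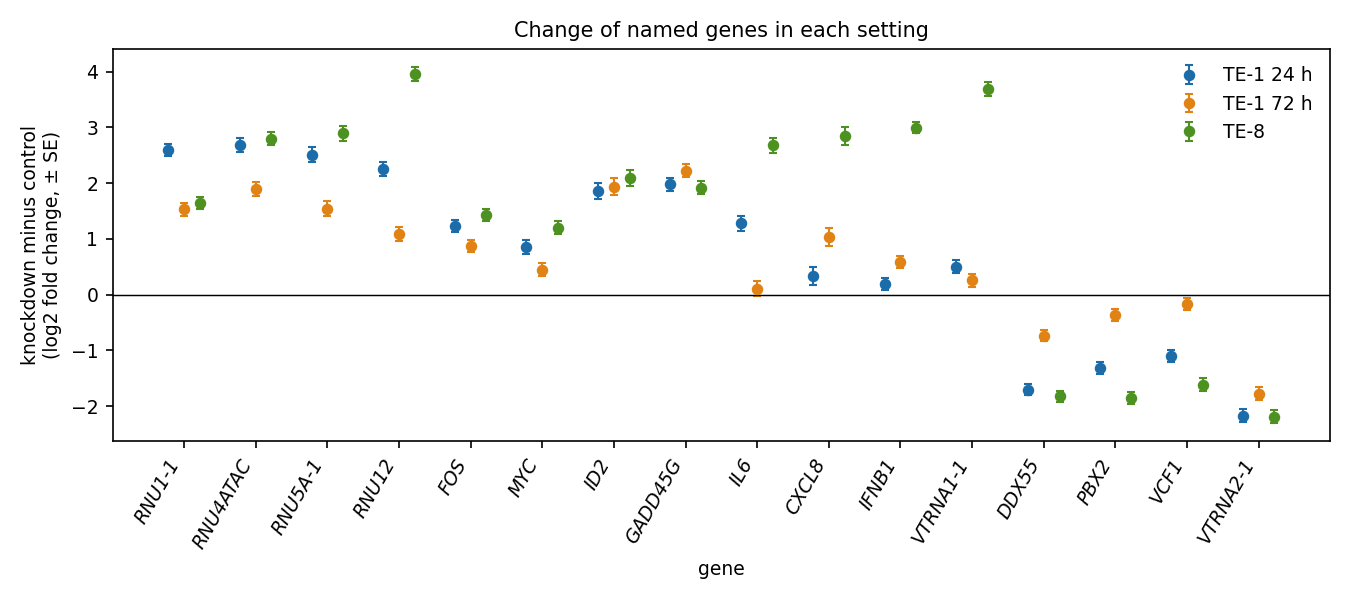
Log2 change between knockdown and control (vertical axis) of genes named for the knockdown comparisons (horizontal axis) in TE-1 at 24 h (blue), TE-1 at 72 h (orange) and TE-8 (green), with bars of 1 SE (n = 3 per group). RNU4ATAC, GADD45G and ID2 lie above 0 and DDX55, PBX2 and VTRNA2-1 below it in all 3 settings, and VTRNA1-1 lies higher in TE-8, at 3.69, than in TE-1.

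**Figure D4:**
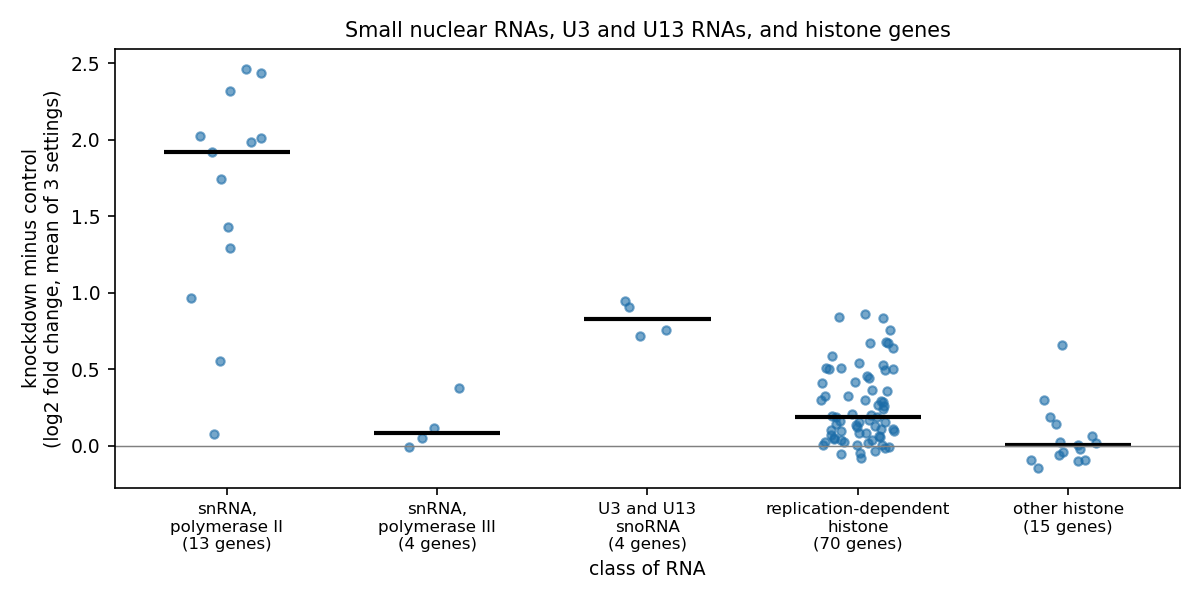
Log2 change between knockdown and control in the mean of the 3 settings (vertical axis) of each gene (points) in classes of RNA chosen after the values were seen (horizontal axis), with the class median as a line. The median of the 70 replication-dependent histone genes is 0.19 and that of the 15 other histone genes 0.01.

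The effects at 72 h and 24 h in TE-1 were compared to ask whether the response changed with time. LFNG, HCFC1R1, KCNT1, a potassium channel gene, LCN2 and RALGPS1 had effects higher at 72 h by 1.57, 1.54, 1.52, 1.51 and 1.47 on the log2 scale. CCDC80, a matrix protein gene, differed by -1.54, RNA5S9, a 5S ribosomal RNA, by -1.49, CPA4, a carboxypeptidase, by -1.46, MIR554 by -1.44 and RNVU1-18 by -1.42. LCN2, for example, was at -0.07 at 24 h and at 1.44 at 72 h, and RNA5S9 at 0.97 and -0.53. limma called 1422 genes, 816 with a higher and 606 with a lower effect at 72 h. Other settings moved some of these values by over 1.5 times: the mean over probes gave 0.61 for LFNG and -0.69 for CCDC80, the authors' values 0.94 for KCNT1 and -0.82 for MIR554, no background correction -0.92 for MIR554, and median scaling -0.90 for RNVU1-18. The count was 2202 under median scaling, with 92.4% of genes higher against 57.4%, 808 with only the compared arrays in the fit, 555 with a normexp offset of 16, 880 without TE-1 knockdown 24 h replicate 1, 946 without TE-1 control 24 h replicate 1 and 945 without TE-1 control 24 h replicate 2 and 72 h replicate 2.

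The TE-8 effect was compared with the mean TE-1 effect to ask whether the lines respond alike. VTRNA1-1 and VTRNA1-2 had effects higher in TE-8 by 3.31 and 3.08, IFNB1 by 2.61, RPPH1 by 2.52 and IFNL1, an interferon of the lambda type, by 2.32. For VTRNA1-1, the target in the control arms, a stronger fall in the TE-8 control cells cannot be told apart from a response to nc886 knockdown. EXT1 differed by -1.33, TSPAN9, a tetraspanin, by -1.24, DKK3, a secreted regulator of Wnt signalling, by -1.17, ATP9A, a lipid flippase, by -1.16 and TM7SF3 by -1.15. IFNB1 was at 0.19 (adjusted p = 0.346) and 0.59 in TE-1, where TE-8 had a rise of 7.97-fold. Its levels, like those of VTRNA1-2, lay under the dim level, where a change shows less, in all TE-1 groups but the 72 h knockdown cells. Those of IFNL1 lay under it in all TE-1 groups. The TE-1 changes of IFNB1 and VTRNA1-2 are thus lower bounds, and the 2.61, 3.08 and 2.32 of these genes are not exact differences. The means over the probes of DKK3 and ATP9A were -0.55 and -0.47. limma called 2158 genes, 1225 with a higher and 933 with a lower effect in TE-8, and 1138 with a normexp offset of 16. Since the time of TE-8 is not given, line and time are not separate in this comparison.

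Among TE-1 control cells, 72 h was compared with 24 h to show what differed between the times without nc886 knockdown. Both groups had received the oligonucleotide against VTRNA1-1. Time is thus not separate from the length of that treatment, nor from the handling of each set of arrays. The largest fall was that of SCD, which makes monounsaturated fatty acids, at -4.92 (30.2-fold, adjusted p = 4.11e-24), and SREBF1, a regulator of lipid synthesis, was at -2.37. CTSZ, a lysosomal protease, was at -3.16, the U3 small nucleolar RNAs SNORD3D and SNORD3A at -2.63 and -2.53, and the transcription factor ZNF503 at -2.45. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 3.95 (adjusted p = 3.76e-24), the cytokine gene LTB by 2.52, the transcription factor MAFF by 2.30, USP14 by 2.04, PLEKHB2 by 2.02 and the lipid droplet gene PLIN2 by 2.01. The rise of ANGPTL4 is a lower bound, as its 24 h level lay under the dim level. Means over probes were smaller for ANGPTL4 (1.59), LTB (1.63), MAFF (0.98), USP14 (1.31), PLEKHB2 (1.19), ZNF503 (-1.26) and SREBF1 (-1.52). Cholesterol synthesis genes had 14 of 25 fallen and 3 risen (15 and 4 adjusted over the list alone, adjusted p = 0.00023, and adjusted p = 0.00983 with an estimated correlation), with DHCR7 at -2.06 and MVK at -1.56. Vault particle and RNA polymerase III genes had 13 of 24 fallen and 1 risen (13 and 2 adjusted over the list alone, adjusted p = 0.00023, and adjusted p = 0.0413 with an estimated correlation), with GTF3C1 and GTF3C5 both at -1.40 and BRF1 at -0.81 (mean over its probes -0.23).

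Another 3 lists were called for time with the preset correlation alone. Fatty acid synthesis genes had 8 of 20 fallen and 3 risen (10 and 4 adjusted over the list alone, adjusted p = 0.0159, and adjusted p = 0.306 with an estimated correlation), with the fatty acid synthase FASN at -1.42 and ELOVL6 at 0.96. Epithelial junction genes had 14 of 28 fallen and 4 risen (14 and 5 adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.306 with an estimated correlation), with TJP3 at -1.77, KRT19 at -1.75 and KRT8 at -1.41. NF-kB genes and targets had 17 of 34 risen and 7 fallen (adjusted p = 0.0434, and adjusted p = 0.61 with an estimated correlation), with the NF-kB subunit REL at 1.39 and the adhesion molecule ICAM1 at 1.20. The NF-kB call was lost in 7 of 13 alternatives, over which the adjusted p ranged from 0.0246 to 0.411: its mean shift was -0.08 under median scaling, 0.24 without TE-1 control 24 h replicate 2, 0.22 without 24 h replicate 3 and 0.21 without 72 h replicate 1. With dim genes left out the junction and fatty acid calls were lost (adjusted p = 0.172 and 0.2, over ranges from 0.00077 and 0.000143). In this comparison limma called 9100 genes, 4109 higher and 4991 lower at 72 h, 560 and 586 of them at least 2-fold, and the groups did not overlap for 35.3% of genes, where chance gives 10%. Under median scaling 15.4% of the called genes were higher, against 45.2%, and the median change of genes above the dim level was -0.28.

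TE-8 control cells were compared with the mean of the TE-1 control groups to describe how the lines differ without nc886 knockdown. Both had received the oligonucleotide against VTRNA1-1. The time of TE-8 is not given, and 9100 genes were called between the times in TE-1 controls. Line is thus not separate from time in this comparison, nor from any batch of arrays, which the labels do not name. H19, a fetal long noncoding RNA, was higher in TE-8 by 7.86, the basal keratins KRT6A and KRT5 by 6.71 and 6.23, COL17A1, which anchors basal cells to their membrane, by 6.44, IFI44, an interferon-induced gene, by 5.35 and FGFBP1 by 5.16. KRT81, a hair keratin, was at -7.51, SUSD2 at -7.16, the actin crosslinker FLNC at -6.96, the skin protease KLK5 at -6.39 and CST6, a protease inhibitor, at -5.83. Means over probes were 3.70 for KRT6A and -3.58 for CST6. The lower line lay under the dim level for H19, KRT6A, KRT5, COL17A1, IFI44, KRT81, FLNC, KLK5 and CST6, and for OASL, IFITM1 and CDH2 below, so these differences are lower bounds. Interferon-stimulated genes had 35 of 38 higher and 2 lower in TE-8 (35 and 2 adjusted over the list alone, adjusted p = 3.55e-24, and adjusted p = 1.66e-05 with an estimated correlation), with OASL at 4.37 (mean over its probes 2.78), IFITM1 at 4.20 and HERC5 at 4.14. Squamous keratins and differentiation genes had 23 of 45 higher and 6 lower (adjusted p = 8.37e-06, and adjusted p = 0.00231 with an estimated correlation), with TP63, the master regulator of squamous cells, at 4.91. DNA replication and S phase genes had 19 of 34 higher and 5 lower (21 and 5 adjusted over the list alone, adjusted p = 0.000216, and adjusted p = 0.00664 with an estimated correlation), with RRM1 at 1.39 and POLA1 at 1.41.

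Another 10 lists differed between the lines with the preset correlation alone. Immediate early and AP-1 genes were mostly lower in TE-8, 19 of 32 against 6 higher (adjusted p = 0.000216, and adjusted p = 0.105 with an estimated correlation), with CCN2 at -4.31 and DUSP1, which switches off MAP kinases, at -3.56. Epithelial-mesenchymal genes had 16 of 35 lower and 8 higher (adjusted p = 0.00872, and adjusted p = 0.105 with an estimated correlation), with the mesenchymal cadherin CDH2 at -5.67. ER chaperone genes had 11 lower and 3 higher of 23 (adjusted p = 0.00317), TGF-beta targets 11 and 8 of 20 (adjusted p = 0.00985) and histones 9 and 6 of 19 (adjusted p = 0.0219). G2/M genes had 23 higher and 8 lower of 38 (adjusted p = 0.000563), MYC targets 19 and 5 of 30 (adjusted p = 0.00317), vault and RNA polymerase III genes 14 and 3 of 24 (adjusted p = 0.00317), heat shock genes 15 and 4 of 23 (adjusted p = 0.014), and hypoxia and glycolysis genes 18 and 9 of 34 (adjusted p = 0.0174). For these 8 lists the values were adjusted p = 0.105, 0.158 and 0.105, then 0.0936, 0.105, 0.0936, 0.0936 and 0.105, with an estimated correlation. limma called 12141 genes between the lines, 6303 higher and 5838 lower in TE-8, 1379 and 1506 of them at least 2-fold. The ER call was lost under median scaling (adjusted p = 0.174, range from 0.00184) and the TGF-beta call there (0.0544) and with dim genes left out (0.0844, range from 0.00613), which also ended the histone (0.0917, range from 0.0152), hypoxia (0.0917, range from 0.000598) and heat shock (0.0844, range from 0.000723) calls.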

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

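The tests of small RNA recovery, of near-identical U1 copies, of the control oligonucleotide and of the 8 cytokine genes under the dim level in every TE-1 group, and all counts over other splits of the arrays, were chosen only after the result was seen.

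Effects that differed between the TE-1 times drew attention because limma called the difference itself for 1422 genes. Under 100 splits of the arrays within settings only the real split reached the real count, and the highest other was 1171. In that other split 2 settings were kept or swapped whole, and over the 67 splits that kept none the highest was 1. The splits mix knockdown and control arrays within each setting, so they ask whether knockdown has any effect. They do not ask whether the effects at the 2 times are equal, so this count does not exclude chance for the difference. The largest differences, 72 h minus 24 h, were LFNG 1.57, HCFC1R1 1.54, KCNT1 1.52, LCN2 1.51 and RALGPS1 1.47, and CCDC80 -1.54, RNA5S9 -1.49, CPA4 -1.46, MIR554 -1.44 and RNVU1-18 -1.42.

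Effects that differed between TE-8 and TE-1 drew attention because limma called the difference for 2158 genes. Of 100 splits 5 gave as many, with up to 3737 genes. These splits do not ask whether the effects in the 2 lines are equal either, so this count does not exclude chance. The split with 3737 also kept or swapped 2 settings whole, which points to the knockdown effects themselves as its structure, and over the 67 splits that kept none the highest was 0. The largest differences, TE-8 minus TE-1, were VTRNA1-1 3.31, VTRNA1-2 3.08, IFNB1 2.61, RPPH1 2.52 and IFNL1 2.32, and EXT1 -1.33, TSPAN9 -1.24, DKK3 -1.17, ATP9A -1.16 and TM7SF3 -1.15.

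Probes without a gene name lie outside the comparisons of genes, yet of 3270 such probes limma called 82 in TE-1 at 24 h (54 higher, 28 lower in knockdown), 93 at 72 h (49 and 44) and 184 in TE-8 (138 and 46).

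The first pattern weighed is the rise of small nuclear RNAs in the knockdown arms. A better recovery or labelling of all small RNA, as the whole cause, would raise small nucleolar RNAs as much. Of 281 measured, the 158 above the dim level had a median change of 0.0604 over the mean of the 3 settings (90th percentile 0.34), 1.22 below that of the 15 small nuclear RNAs above it, taken as 10 families (permutation p = 0.0001, the smallest that 10000 permutations can give). In TE-8 the class did shift up, with 57 risen and 1 fallen (camera adjusted p = 4.26e-08, and 0.00436 with an estimated correlation) and a median of 0.13 above the dim level, so whether labelling added to the rise there cannot be told apart from a change in the cells. Normalization as the whole cause is argued against by a lowest median of 0.40 over the 3 settings and 7 scalings, and probes of near-identical U1 copies reading the same RNA by genes of 4 families other than U1 risen in all 3 settings. Whether the control oligonucleotide lowered these RNAs, rather than the nc886 oligonucleotide raising them, cannot be told apart: the median difference of 1.43 lies between treated arms, and no untreated arrays are in the series. A response to loss of nc886 thus stays open beside an effect of the control oligonucleotide. So does a change in how these RNAs were primed and labelled, as the labels do not state how the first strand was primed.

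The second pattern is the larger rise of cytokine and interferon genes in TE-8 than in TE-1, taken as 22 genes of 90 candidates with a called difference, with median changes of 1.01 and 0.20. If the genes lay under the background in TE-1 the difference would be a floor effect. Of the genes, 63.6% (14 genes) had a mean above the dim level in a TE-1 group, control or knockdown. The highest TE-1 group means of IL6, IFIT2, BIRC3 and NFKBIA were 10.7, 10.4, 12.2 and 12.8, far above it, which argues against a floor as the whole cause. IFNB1 passed only by its 72 h knockdown group, with a mean of 7.07. For IFNB1 and for the other 8, IFNL1, PTGS2 and IL1B among them, a floor effect cannot be told apart from a lack of response. The medians only describe the set, as its genes were picked by their difference. Over all 90 candidates they were 0.13 in TE-8 and 0.09 in TE-1, and 2 had a called difference the other way. Of the 90, 58 had a larger effect in TE-8. The mean shift of the NF-kB list was 0.63 in TE-8 against 0.25 at both TE-1 times, and that of the interferon-stimulated list 0.22 against 0.00 at 24 h and 0.19 at 72 h (medians 0.09, 0.01 and 0.14). If 1 TE-8 array made it, leaving that array out would end most calls, but at least 86.4% (19 genes) kept theirs. The time after treatment stays open: 2 genes of the set differed between the TE-1 times, and as the time of TE-8 is not given, time and line cannot be told apart. A difference between the lines themselves stays open as well.

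The third pattern is that the TE-1 72 h effect resembled the others less, with a correlation of log2 changes of 0.24 with TE-1 at 24 h against 0.53 between TE-1 at 24 h and TE-8, across genes that are not independent replicates. An outlying control array is argued against as the whole cause, since without TE-1 control 72 h replicate 2 the correlation was 0.27, within 0.187 to 0.279 over all left-out arrays. Quantile normalization of arrays that differ in their bright signals is argued against likewise, since under median scaling it was 0.20. Both values stay under the bound of 0.4 set beforehand. Time after treatment, which the design names, stays open as a biological difference that was not tested apart from the day or handling of the 72 h arrays.

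For the other counts, splits of the 6 arrays of a comparison number 10, too few for a share under 0.05, and in each case 1 split, the real one, reached the real value. Genes called were 1967 against a highest other of 12 in TE-1 at 24 h, 2425 against 7 at 72 h, 3691 against 0 in TE-8 and 9100 against 0 for time. Lists called were 11 against 10, 16 against 9, 11 against 9 and 5 against 2, and with an estimated correlation 5, 12, 6 and 2 against 0 each. Under 100 splits a chance assignment of these arrays to groups can be excluded for the mean effect (4478 genes, highest other 3076, with 2 settings kept or swapped whole, and 0 where none was kept). The same holds for genes risen in all 3 settings (181 against 1), for those fallen (76 against 0) and for genes between the lines (12141 against 10152), each reached by 1 split. The splits within settings ask only whether knockdown has any effect. They do not ask whether the settings share more genes than separate effects would give. Such an assignment cannot be excluded for the lists between the lines, where 7 of 100 splits gave as many as 13 (up to 15) and 9 gave as many as 3 with an estimated correlation (up to 10). The splits between the lines do not separate line from time or batch. As the labels do not say whether replicates were separate cultures, no split covers chance between cultures.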

How the results depend on the processing

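Alternatives chosen after seeing the data were leaving out dim genes, a normexp offset of 16, normalization within sets of 6, and leaving out TE-1 control 24 h replicate 2 with TE-1 control 72 h replicate 2. Of the planned ones, the stricter detection filter and the slide block were not run, as the files give no detection p-values or slides, and no detection filter is the main setting. Normalization within sets and the authors' table give no value for time or line. For named genes 7090 values under alternatives other than left-out arrays kept direction and side of the threshold, 146 became called, 253 lost their call and 2 reversed; with 1 array left out these were 4278, 31, 209 and 0. For lists they were 978, 28, 33 and 1, then 828, 9, 21 and 0. No background correction, normalization within lines or sets, the authors' table, all probes, means of probes and an intensity trend kept every count within 1.5 times. With an estimated correlation the lists called were 5 in TE-1 at 24 h, 6 in TE-8, 2 for time and 3 for line, and with fry 16 for time and 25 for line. Median scaling gave 2202 genes differing between TE-1 times, 11 lists for time and 19 genes fallen in all 3 settings; the cause was not tested. Only the compared arrays in the fit gave 976 genes against 2425 in TE-1 at 72 h, but 5606 against 3691 in TE-8. They gave 808 differing between TE-1 times and 35 fallen in all settings. The main fit takes a common spread per gene over all groups. Replicate correlations were 0.988 to 0.994 in TE-1 control 72 h and 0.997 in both TE-8 groups. The p-values of these settings thus depend on that choice, and the cause was not tested further. Leaving out dim genes, which tests fewer, gave 6 lists in TE-1 at 24 h and 2 for time. A normexp offset of 16 gave 1091 genes in TE-1 at 24 h, 1293 at 72 h, 555 and 1138 differing between times and lines, and 107 risen and 31 fallen in all settings; the cause was not tested. Without both TE-1 control arrays in doubt (24 h replicate 2, 72 h replicate 2) there were 1529 genes in TE-1 at 72 h, 945 differing between times and 46 fallen. With each array left out in turn, counts ranged from 1306 to 1845 in TE-1 at 24 h, 1471 to 3137 at 72 h, 2738 to 2968 in TE-8, 3939 to 4780 for the mean, 880 to 2102 and 1489 to 2448 for differences by time and line, 8036 to 8655 for time, 10909 to 12271 for line, and 144 to 192 risen and 53 to 79 fallen in all settings. Lists ranged from 8 to 11, 14 to 16, 10 to 12, 4 to 6 and 13 to 14 in TE-1 at 24 h, at 72 h, in TE-8, for time and for line. The lowest count in TE-1 at 24 h came without TE-1 control 24 h replicate 1 (1306, and 1310 without TE-1 knockdown 24 h replicate 1). At 72 h it came without TE-1 control 72 h replicate 2 (1471). For the difference by time it came without TE-1 knockdown 24 h replicate 1 (880, and 946 without TE-1 control 24 h replicate 1). Without TE-1 control 72 h replicate 3 the last 2 counts rose, to 3137 and 2102, so fewer samples alone do not account for the shifts. Camera's direction turned to down for the heat shock list in TE-1 at 24 h under median scaling (adjusted p = 0.00813, against 0.955 up in the main setting), though its mean shift was negative in both (-0.18 and -0.00), and the fold turned for FBLN1 with the mean of its probes (-0.0111 in TE-1 at 72 h, -0.18 for time); the cause was not tested. Under median scaling the median change of genes above the dim level was -0.11 in TE-1 at 24 h, 0.07 at 72 h, 0.17 for the difference by time, -0.28 for time and 0.21 for line. Replicate numbers did not pair the arrays: deviations from the group means of arrays with the same number correlated at -0.44 to 0.24. With the number as a block the counts were 1782, 2248, 3505, 4318, 1305, 1995, 9591 and 12225 for the comparisons in the same order, and the lists 11, 16, 11, 5 and 13. Signal over background limits dim genes, as a fold near the array minimum is compressed by the offset of 50.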

Other observations

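The tests of histone messages, of small nucleolar RNAs, of neighbours, of the polymerase that makes each small nuclear RNA and of own promoters in each setting were chosen only after the result was seen.

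Of 281 small nucleolar RNAs 10 rose and 5 fell in TE-1 at 24 h, 9 rose and 14 fell at 72 h, and 57 rose and 1 fell in TE-8, with median changes of 0.03, -0.02 and 0.08. Of 664 long noncoding RNAs 30, 23 and 72 rose and 4, 11 and 5 fell in these settings. Of 563 microRNA precursors 1, 3 and 5 rose and 2, 5 and 1 fell. CCDC80, a matrix protein gene, rose in all 3 settings, by 2.02, 0.48 and 2.70, and DKK3, a secreted regulator of Wnt signalling, rose in TE-1 at 24 h by 0.81 and at 72 h by 1.27 and was at -0.13 in TE-8 (adjusted p = 0.627).

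Between the lines, TE-8 and TE-1 controls also differed in genes of the cytokine set named above. IFIT2 was higher in TE-8 controls by 2.02. PTGS2 was higher there by at least 3.54 and IL1B, an inflammatory cytokine, by at least 2.07, as their TE-1 levels lay under the dim level, and IL6, whose TE-8 control level did, was at -3.22 or lower. In the knockdown comparisons IL6 was at 2.68 in TE-8 and at a mean of 0.69 in TE-1.

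A hypothesis on class is that RNAs made without a poly(A) tail may have gained signal together, histone messages included. Replication-dependent histone genes, taken by their symbols, make messages that as a rule lack such a tail. They had a median change of 0.19 over the mean of the 3 settings, against -0.00 in genes matched on level (70 genes, 36 risen, 0 fallen, permutation p = 0.0001, the smallest that 10000 permutations can give). The 15 other histone genes, whose messages as a rule carry a tail, had a median of 0.01 (permutation p = 0.19). The tails themselves were not measured. Small nucleolar RNAs lack a tail too. In TE-8 the 158 above the dim level had a median of 0.13 (permutation p = 0.0001 against genes matched on level), where histone messages above it had 0.34. In TE-1 at 24 h they had 0.0419 (permutation p = 0.0004) against 0.28 for histone messages. The permutations take genes as independent. At 24 h camera did not call the 281 small nucleolar RNAs (adjusted p = 0.23, and 0.542 with an estimated correlation). The hypothesis stays open there, without a called shift of the class. At 72 h the 158 had -0.0555 (permutation p = 1) against 0.20, which argues against a joint gain at that time. The histone values are consistent with the hypothesis, but they do not separate a change in the cell from a change in how such RNAs were primed and labelled.

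A hypothesis on the polymerase is that only the small nuclear RNAs made by RNA polymerase II may have risen. Of those above the dim level polymerase II makes 12, among them near-identical U1 copies, and polymerase III 3 (RN7SK, RNU6-1 and RNU6ATAC), so the copies were averaged into 7 and 3 families. In TE-1 at 24 h 11 of the 12 and 0 of the 3 genes rose, and the means over families differed by 1.84 (exact permutation p = 0.00833 over 120 regroupings, two-sided). At 72 h 9 and 0 rose and RNU6-1 and RNU6ATAC fell, with a difference of 1.26 (exact permutation p = 0.0417). In TE-8 the difference was 1.61 (exact permutation p = 0.0333), but all 12 and all 3 rose. RN7SK rose by 1.19, RNU6-1 by 0.61 and RNU6ATAC by 0.62, which argues against the hypothesis in that line. RPPH1, which polymerase III makes, rose there by 3.27 but is not one of the small nuclear RNAs tested. Its TE-8 effect was 2.52 above its mean TE-1 effect, so that effect was above 0 too. RNAs of polymerase III outside the class were not tested as a set in either line. Small nucleolar RNAs with promoters of their own would be expected to move with those of polymerase II. The 4 measured were SNORD3A, SNORD3C and SNORD3D of the U3 type, which are near-identical copies, and SNORD13. Their median change was 0.83 over the mean of the 3 settings (permutation p = 0.0002 over 10000, against genes matched on level). The permutation took the copies as separate genes, which makes its p too small. TE-8 carried the median, at 1.82 with 4 risen. At 72 h the median was 0.57 with 2 risen. At 24 h it was 0.21, with SNORD3A at 0.13, SNORD3C at 0.29, SNORD3D at -0.20 and only SNORD13 called, at 0.61, while the small nuclear RNAs had a median of 1.64, so a joint rise was not shown there.

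A hypothesis on read-through is that transcripts running past small nuclear RNA genes could raise their neighbours. The 174 coding genes next to small nuclear RNA genes had a median change of -0.00578 (permutation p = 0.33 against genes matched on level), with 23 risen and 19 fallen. The 19 beside risen small nuclear RNA genes had one of -0.07 (permutation p = 0.91), with 2 risen and 3 fallen. No shared rise of the neighbours was thus seen. As genes on either side were taken, the medians do not decide about read-through at single genes.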
